A study of Homo sapiens with 20 samples.

How the data were processed

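CD34+ cells, the fraction of blood that holds hematopoietic stem and progenitor cells, were isolated from human umbilical cord blood and incubated ex vivo with 10 µM 16,16-dimethyl prostaglandin E2 (dmPGE2, a stabilised analog of prostaglandin E2) or with the vehicle dimethyl sulfoxide (DMSO). The incubation lasted 1 h at 4 °C or 2 h at 37 °C. Each of the 20 samples was measured on 1 Affymetrix expression array of 54675 probe sets. Per the labels' protocols, total RNA was amplified in a protocol of more than one round before biotin labelling.

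Per the submitters' processing notes, the values were made with Affymetrix Expression Console 1.1 and RMA, which corrects background, normalises arrays by quantiles and summarises each probe set. The deposited values are on the log2 scale and ran from 2.19 to 15.3. The deposited arrays fell apart by incubation condition in their distribution: array medians lay between 6.51 and 6.57 at 4 °C and between 6.22 and 6.31 at 37 °C. Whether the conditions were normalised together is not given in the sources used here. Comparisons of drug with vehicle stay within a condition, and their count at 37 °C was 449 after quantile normalisation over all arrays and 400 after centring, in place of 436. Levels set across conditions depend on it more directly.

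Probe sets were named from the platform annotation. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. The gene identifiers of 41043 of the named probe sets were found in the RefSeq gene table, which changed 0 symbols. Probe sets at or above the 40th percentile of the array in at least 3 arrays were kept (37236), and each gene was represented by its probe set with the highest mean over all arrays, which gave 15281 genes. No value was transformed further.

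Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over 15281 genes, adjusted p under 0.05). The fit held 4 group means over all 20 arrays, which shared 1 estimate of the spread. Contrasts were drug against vehicle at 37 °C (7 against 7), drug against vehicle at 4 °C (3 against 3), the difference between these responses, and vehicle at 37 °C against vehicle at 4 °C. Errors of log2 fold changes are standard errors (SE) of this fit. The submitters describe the samples as biological replicates. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over 17 pathway lists or over 10 lists of cell type markers. Where members of a pathway list are counted, the count adjusted over the list alone is given beside it. No array duplicated another: the highest correlation between 2 arrays was 0.998, and at least 99.8% of probe sets differed between any 2 arrays.

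Replicate numbers in the labels were checked for pairing. Arrays of drug and vehicle with the same number deviated together from their group means, with correlations of 0.488 to 0.865 over the 7 numbers at 37 °C and of 0.812 to 0.895 over the 3 numbers at 4 °C. All exceeded the limit of 0.1 set for pairing, and 6 of the 7 numbers at 37 °C correlated best with their own partner. The numbers were therefore taken to pair drug and vehicle within a condition, and a fit with the replicate number as a block is given beside the counts, lists and genes named at 37 °C where it changed a call. For the difference between the conditions it is given for the lists, for some genes, and otherwise as a count of genes.

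Both fits were tested on simulated data of 15281 genes in which 200 genes were changed. For the comparison at 37 °C, the fit without the block recovered 19.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 97% of those changed 4-fold, and 0.9% of its calls were unchanged genes. The blocked fit recovered 79.1%, 92.5% and 100%, but 13.4% of its calls were unchanged genes, above the nominal 5%. For the comparison at 4 °C, the fit without the block recovered 1.5%, 23.9% and 75.8%, and the blocked fit 26.9%, 80.6% and 100%, with 2.8% of calls unchanged genes.

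The genes named were chosen by a rule fixed before the data were examined. It takes the 15 largest log2 fold changes in each direction among genes past the threshold for each drug comparison, and the 8 largest in each direction for the other contrasts. Where fewer than 5 genes passed in a direction, the 5 with the smallest p are named. For each pathway list it takes up to 4 members with the smallest p, which are named at 37 °C. In the other comparisons only some of these are named, and some genes outside the rule are named as well. The prostaglandin receptors PTGER1 to PTGER4, CREM, NR4A2, CXCR4, BIRC5 and CCND1 are always named, and Y-linked genes and XIST never. Genes with only a locus name are counted and need not be named. The main designs, the lists and most alternative settings were also fixed before the data were examined. Alternatives covered the filter, normalisation, probe set choice, variance model, array weights, arrays in the fit, threshold, pairing, and leaving out arrays. Probe sets with several or no gene symbols were left out of the comparisons. The number of arrays limits the precision throughout. Figures were drawn with matplotlib 3.10.9.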

Results

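Expression was measured in 4 groups of cord blood CD34+ cells: 7 samples with dmPGE2 and 7 with vehicle after 2 h at 37 °C, and 3 samples with each after 1 h at 4 °C. The title states that prostaglandin pathway activation was to be assessed. One RNA quality measure of the arrays, the log2 difference between 3′ and 5′ probe sets of ACTB, averaged 4.74 ± 0.48 (SD, n = 7) with dmPGE2 and 4.97 ± 0.37 (SD, n = 7) with vehicle at 37 °C. Within pairs it differed by -0.23 (two-sided exact permutation test, p = 0.0938, smallest possible 0.0156). At 4 °C the difference was -0.41 over 3 pairs (two-sided exact permutation test, p = 0.5, smallest possible 0.25). The same measure of GAPDH differed within pairs by 0.001 at 37 °C (two-sided exact permutation test, p = 0.984) and by -0.34 at 4 °C (two-sided exact permutation test, p = 0.25, the smallest possible). Both mean differences at 4 °C came largely from the vehicle array of replicate 3. It was at 1.58 for GAPDH and 5.53 for ACTB. Vehicle replicates 1 and 2 were at 0.72 and 0.70 for GAPDH and at 5.11 and 4.52 for ACTB.

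The first comparison asked which genes responded to dmPGE2 in 2 h at 37 °C. The largest rise was that of TAC1, which encodes the substance P precursor, with a log2 fold change of 5.84 ± 0.64 (SE, n = 7 per group) or 57.1-fold. DUSP4, a phosphatase of MAP kinases, rose by 5.20 ± 0.62 and the non-coding RNA LINC00473 by 4.55 ± 0.21. The transcription factors CREM (3.87 ± 0.28, 14.6-fold), NR4A2 (3.76 ± 0.34) and NR4A3 (3.34 ± 0.44) and the kinase SIK1 (3.71 ± 0.17) rose as well. The neutrophil-attracting chemokines CXCL6 (4.08 ± 0.39) and CXCL5 (3.90 ± 0.69) increased, as did SV2C (4.47), GEM (4.41), TKTL1 (4.40), carbonic anhydrase CA2 (3.45), the activin subunit INHBA (3.26) and ZNF331 (3.23). Each of these 15 genes was higher with dmPGE2 in 7 of 7 pairs. All probe sets of DUSP4 (3), CREM (5), NR4A2 (3) and NR4A3 (3) passed as higher, whereas of SIK1 1 of 2 did (other -0.01).

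Decreases were smaller. The largest was that of SMAD6, an inhibitor of BMP signalling, at -2.17 ± 0.30 (SE, n = 7 per group), followed by PARP8 (-1.93 ± 0.37) and the nucleotide kinase CMPK2 (-1.67 ± 0.40). The pro-apoptotic gene BMF fell by 1.55 ± 0.21 on the log2 scale. MGAT4A (-1.65), RGS19 (-1.62), INKA1 (-1.55), CALHM2 (-1.51), PPARGC1B (-1.51), STAM2 (-1.49), ARHGAP5 (-1.47), TMEM200A (-1.46) and CYTH4 (-1.46) also fell, and each of these 13 genes was higher with dmPGE2 in 0 of 7 pairs. A further 2 of the 15 largest decreases carry only a locus name. Several decreases rest on 1 probe set. Of SMAD6, 1 of 3 probe sets passed and the others lay as high as -0.001, and of PARP8 1 of 2 (other -0.09). For MGAT4A, PPARGC1B, STAM2 and ARHGAP5, 1 probe set passed of 3, 4, 3 and 4, with the others as high as -0.15, 0.12, 0.14 and 0.14. CALHM2 passed with 2 of 2 and CYTH4 with 2 of 3. The call of CMPK2 was lost without any 1 of 4 of the 14 arrays (adjusted p up to 0.0584) and that of PPARGC1B without any 1 of 8 (up to 0.0715).

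In total 436 of 15281 genes passed the threshold (limma, adjusted p under 0.05), 282 higher and 154 lower, and 259 of them changed at least 2-fold. The number of lower genes was 91, 98 or 102 without replicate 2 or 3 of the vehicle group or replicate 6 of the drug group, 77 without both arrays of replicate 3, and 255 with array weights. With the replicate block 4380 genes passed, 1396 higher and 2984 lower, and the 436 were among them. Calls at 37 °C described above and below as lost without single arrays are those of the fit without the block. With the block and all arrays these genes passed. The blocked count is open to the excess of false calls seen on simulated data. Only 200 of 15281 genes were changed there, so the share of 13.4% need not hold for a count of 4380. A blocked fit of the arrays at 37 °C alone called 3679 genes, and the 436 were among them. At least 1.5-fold, the blocked count of 4380 held 653 higher and 901 lower genes.

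**Figure D1:**
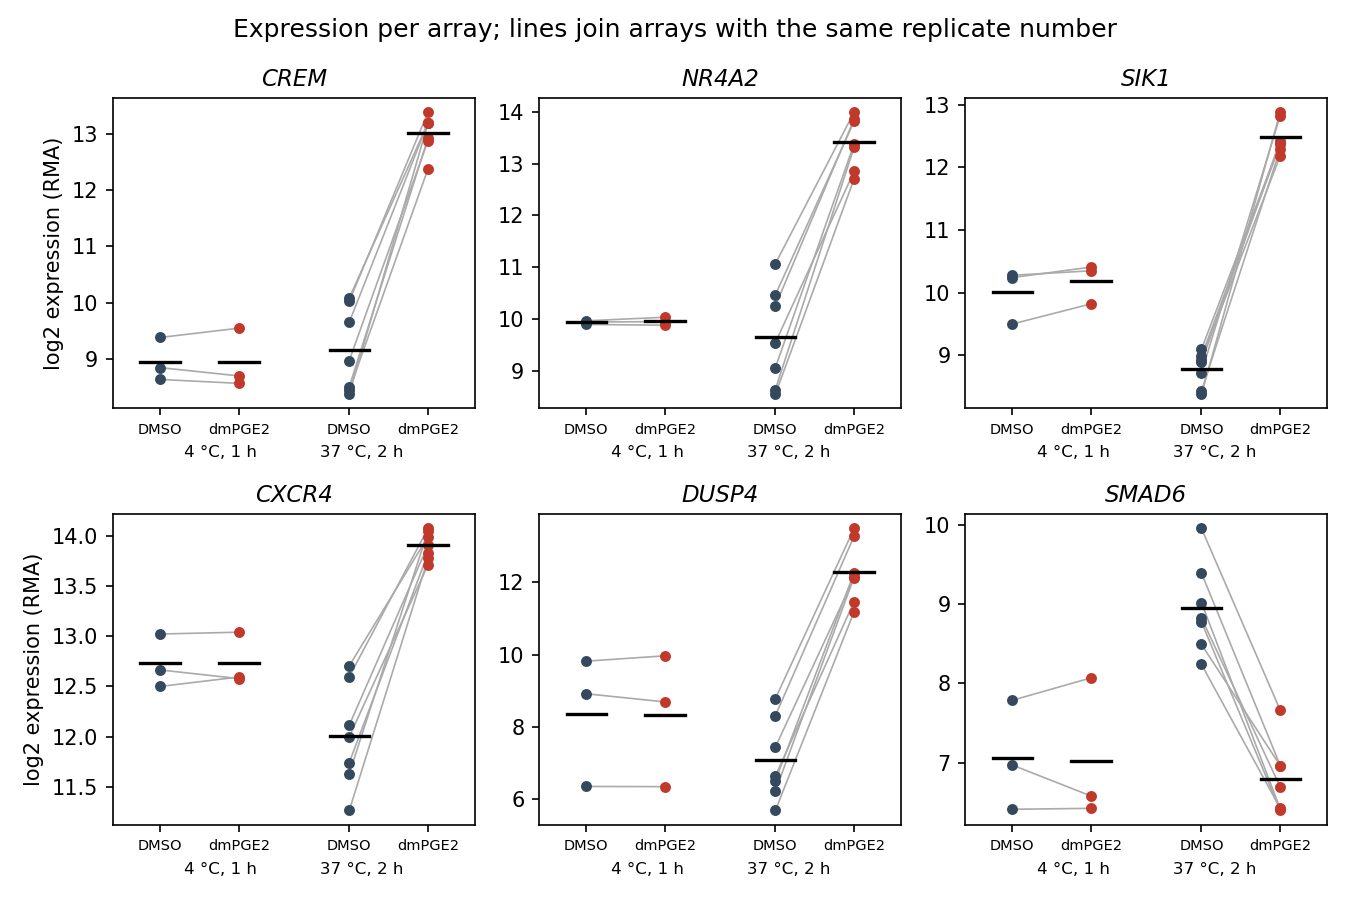
Expression on the log2 scale in each array for 6 genes, with vehicle in dark blue and dmPGE2 in red. Grey lines join arrays with the same replicate number and black bars are group means (n = 3 per group at 4 °C and n = 7 at 37 °C), which for NR4A2 were 13.4 with dmPGE2 and 9.66 with vehicle at 37 °C, and 9.96 and 9.94 at 4 °C.

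Among the prostaglandin E2 receptors, PTGER4 rose at 37 °C by 1.83 ± 0.48 (SE, n = 7 per group, adjusted p = 0.0444), a call lost without any 1 of 10 of the 14 arrays, with adjusted p up to 0.0968, and carried by 1 of 2 probe sets (other 0.55). PTGER1 (0.10 ± 0.13), PTGER2 (-0.40 ± 0.34) and PTGER3 (0.37 ± 0.52) did not pass. With the replicate block PTGER3 had an adjusted p of 0.0453 and PTGER4 one of 1.06e-05. PTGER4 was higher with dmPGE2 in 7 of 7 pairs. The list of prostaglandin receptors and enzymes had 2 of 17 measured members higher, PTGER4 and the synthase PTGES (0.79 ± 0.21, a call lost without any 1 of 12 arrays, adjusted p up to 0.107), and 4 higher and 1 lower adjusted over the list alone. Cyclooxygenase PTGS2 (1.67 ± 0.46, adjusted p = 0.0543) and ALOX5AP (0.72 ± 0.22, adjusted p = 0.0914) did not pass, but did with the block (adjusted p = 0.00022 and 1.17e-05). The list was called higher by camera (adjusted p = 0.0159), not with an estimated correlation (adjusted p = 0.0946), though again with the block (adjusted p = 0.0427 with an estimated correlation).

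Targets of cyclic AMP and CREB formed the list with the largest change. Of 19 measured members 12 were higher and 0 lower, or 15 higher adjusted over the list alone, with a median log2 fold change of 1.88. SIK1, CREM, FOSL2 (2.65 ± 0.20) and GEM had the smallest p. The cyclic AMP-degrading phosphodiesterases PDE4B (3.02 ± 0.26), PDE4A (2.11 ± 0.37) and PDE4D (1.88 ± 0.24) were in this list. camera gave an adjusted p of 1.68e-38, and 5.79e-06 with an estimated correlation. The list of cyclic AMP signalling components was not called (camera adjusted p = 0.426): of 27 members 2 were higher, AKAP12 (3.17 ± 0.48) and PDE8A (1.02 ± 0.19, 1 of 3 probe sets, others down to -0.16), and 1 was lower, RAPGEF3 (-0.63 ± 0.17, a call lost without any 1 of 10 arrays, adjusted p up to 0.111), or 3 and 2 adjusted over the list alone. PKIA, an inhibitor of protein kinase A, was at 1.37 ± 0.40 (adjusted p = 0.077, with the block 1.75e-06).

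Immediate early genes had 7 of 29 members higher and 0 lower, or 12 higher adjusted over the list alone, with a median of 0.79. Besides DUSP4 and FOSL2 they included NR4A1 (1.71 ± 0.16) and DUSP2 (2.15 ± 0.29). This list shares members with the cyclic AMP targets, among them FOSL2, ATF3 and DUSP1, so the calls of these lists are not independent. The hypoxia list had 5 of 19 members higher, or 7 adjusted over the list alone: ANKRD37 (2.04 ± 0.35), VEGFA (1.87 ± 0.39), the glucose transporter SLC2A3 (1.61 ± 0.34) and the glycolytic regulator PFKFB3 (1.11 ± 0.23) had the smallest p. Sterol synthesis had 3 of 13 higher, or 5 adjusted over the list alone, with SC5D at 2.25 ± 0.33, STARD4 at 1.52 ± 0.29 and INSIG1 at 0.96 ± 0.26. INSIG1 restrains sterol synthesis, and its call was lost without any 1 of 10 arrays (adjusted p up to 0.111). DHCR7 was at 0.61 ± 0.22 (adjusted p = 0.185, with the block 0.000605). These 3 lists and the cyclic AMP targets were the 4 lists called both by camera at the preset correlation and with an estimated correlation, where the adjusted p was 0.0388 for immediate early genes, 0.00722 for hypoxia and 0.0106 for sterol synthesis.

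A further 4 lists besides prostaglandin genes were called higher only at the preset correlation. NF-κB targets and cytokines had 5 of 24 members higher (7 higher and 1 lower adjusted over the list alone): the cytokines OSM (2.00 ± 0.21) and LIF (1.79 ± 0.31) and the chemokines CXCL1 (2.08 ± 0.25), CXCL2 (2.61 ± 0.46) and CXCL3 (1.49 ± 0.27). The adjusted p was 0.0819 with an estimated correlation. TGF-β, BMP and Notch genes had 5 higher and 1 lower of 21 (6 and 2 adjusted over the list alone). The Notch ligand JAG1 (1.69 ± 0.28) and the Notch targets NRARP (1.58 ± 0.29) and HES4 (1.45 ± 0.27) rose while SMAD6 fell, and the adjusted p was 0.123 with an estimated correlation. Cytokine receptors had 2 of 20 higher (2 higher and 1 lower adjusted over the list alone), TNFRSF1B (2.95 ± 0.29) and the signalling inhibitor SOCS1 (1.23 ± 0.25, 1 of 3 probe sets, others down to -0.03), with an adjusted p = 0.119 with an estimated correlation. IFNGR2 was at -0.70 ± 0.20 (adjusted p = 0.0683) and CISH at -0.24 ± 0.11 (adjusted p = 0.323), and both passed with the block (adjusted p = 3.18e-05 and 0.0371). The unfolded protein response had 1 of 18 higher, HERPUD1 (0.55 ± 0.12), or 2 adjusted over the list alone, with an adjusted p of 0.0819 with an estimated correlation. DNAJB9 (0.67 ± 0.21), XBP1 (0.55 ± 0.20) and TRIB3 (-0.46 ± 0.27) did not pass without the block and did with it (adjusted p = 0.000208, 0.00105 and 0.00106). With the block these 4 lists were called both ways, at adjusted p = 0.0427 or 0.0429 with an estimated correlation.

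Other lists were not called as a whole, though single members changed. camera gave an adjusted p of 0.225 for homing and adhesion, 0.178 for survival, 0.707 for the cell cycle, 0.178 for Wnt, 0.292 for interferon response, 0.426 for primitive hematopoietic genes and 0.0993 for heat shock. In the homing and cyclic AMP component lists the median lay below 0 and the mean above, and in the cell cycle list both lay below 0 while camera ranked it upward. Among homing and adhesion genes, 2 of 22 were higher, also adjusted over the list alone: CXCR4, the receptor that retains stem cells in the marrow, at 1.90 ± 0.19 or 3.73-fold (adjusted p = 3.67e-06), and S1PR1 at 1.89 ± 0.37. The integrins ITGAL (-0.51 ± 0.20) and ITGB1 (0.33 ± 0.16) passed only with the block (adjusted p = 0.00333 and 0.0467). Among survival genes, 3 were higher and 1 lower of 19 (4 and 1 adjusted over the list alone): BCL2L11 (1.94 ± 0.33) and BIK (0.87 ± 0.23, a call lost without any 1 of 11 arrays, adjusted p up to 0.102), which promote apoptosis, BCL2A1 (1.67 ± 0.34), which opposes it, and BMF. BIRC5, or survivin, was at 0.07 ± 0.18 (adjusted p = 0.951). Cell cycle genes had 1 of 31 higher, also adjusted over the list alone, the cyclin-dependent kinase inhibitor CDKN1A (1.36 ± 0.19). AURKA (0.81 ± 0.32), MCM3 (-0.54 ± 0.23) and CCND2 (0.48 ± 0.23) passed only with the block (adjusted p = 0.000103, 0.00115 and 0.00729). Cyclin D1, CCND1, was at 0.44 ± 0.32 (adjusted p = 0.654).

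Wnt pathway genes had 2 of 26 higher, also adjusted over the list alone, the receptor FZD1 (0.97 ± 0.23) and the repressor TLE1 (0.64 ± 0.15). Their calls were lost without any 1 of 2 and of 5 arrays (adjusted p up to 0.0588 and 0.0628). DVL2 (-0.57 ± 0.23) and ZNRF3 (-0.36 ± 0.16) passed only with the block (adjusted p = 0.00161 and 0.0425). Interferon response genes had 2 of 19 higher (2 higher and 1 lower adjusted over the list alone), ISG15 (1.38 ± 0.26) and MX2 (1.13 ± 0.28, a call lost without any 1 of 10 arrays, adjusted p up to 0.0735). RSAD2 (-0.74 ± 0.24) and IRF1 (-0.73 ± 0.27) passed only with the block (adjusted p = 9.43e-05 and 0.00158). Of 23 genes of primitive hematopoietic cells 0 passed with the probe set chosen, or 2 higher and 2 lower adjusted over the list alone. TAL1 (1.00 ± 0.31), KIT (0.82 ± 0.24), LMO2 (-0.75 ± 0.22) and GFI1 (-0.59 ± 0.16) had the smallest p and passed with the block (adjusted p = 0.000701, 0.000471, 0.00253 and 0.00221). With every probe set tested, 1 of 2 passed without the block for LMO2 (the one not chosen, at -2.01) and 1 of 4 for TAL1 (range -0.22 to 1.57). Of 14 heat shock genes 0 passed, also adjusted over the list alone. With the block this list was called higher (camera adjusted p = 0.00183, 0.0429 with an estimated correlation), with DNAJB4 at 0.81 ± 0.57, HSPH1 at 0.65 ± 0.52 and HSPA4 at 0.43 ± 0.29 passing (block adjusted p = 0.000151, 0.000482 and 0.0216). DNAJA1 was at 0.26 ± 0.27. The arrays of replicate 5 stood apart in this list in both groups. Among the list members named above, PTGES and HERPUD1 passed with 1 of 2 probe sets (others 0.26 and 0.21), TLE1 with 1 of 3 (range 0.36 to 0.64) and NR4A1 with 2 of 3 (range 0.14 to 1.71). Of DNAJB9, 1 of 3 passed without the block (range 0.47 to 0.71).

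Of the 10 lists of markers of other cell types (erythroid, T, B and NK cells, monocytes, granulocytes, megakaryocytes and platelets, mast cells with basophils and eosinophils, dendritic cells, endothelial and stromal cells) 0 were called by camera at 37 °C, with or without the block. fry called 0, and with the block 2, the dendritic cell and NK cell lists (adjusted p = 0.000141 and 0.0323). GZMB, which is in the NK cell and the dendritic cell list, was the 1 marker past the threshold (1.09 ± 0.22).

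**Figure D2:**
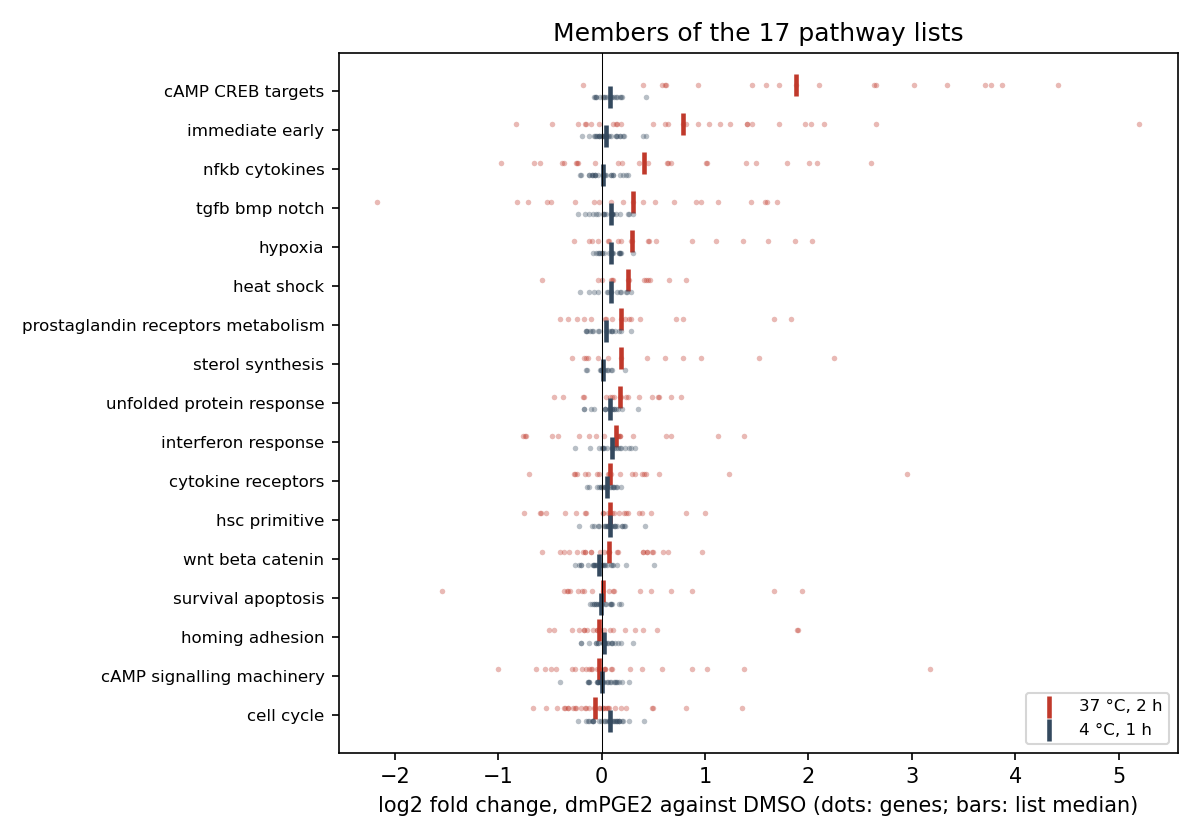
Log2 fold changes of dmPGE2 against vehicle for the members of the 17 pathway lists, at 37 °C in red and at 4 °C in dark blue. Dots are genes and vertical bars are list medians, which at 37 °C ranged up to 1.88 for the cyclic AMP and CREB targets and at 4 °C up to 0.10.

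The comparison at 4 °C asked whether 1 h in the cold was enough for a response. None of the genes named above passed there. CREM was at -0.02 ± 0.43 (SE, n = 3 per group), NR4A2 at 0.02 ± 0.51, CXCR4 at 0.01 ± 0.29 and SIK1 at 0.19 ± 0.25. These SE use the spread shared by all 20 arrays. In the 6 arrays alone with the block, the 95% interval of the fold change was 0.84 to 1.16 for CREM. It was 0.88 to 1.17 for NR4A2, 0.87 to 1.16 for CXCR4 and 0.98 to 1.32 for SIK1. Others lay further from 0: TKTL1 at -0.55 ± 0.39 (higher in 0 of 3 pairs, adjusted p = 1.00, and 0.889 in the 6 arrays alone with the block), AKAP12 at -0.40 ± 0.74, CA2 at 0.35 ± 0.51 and CMPK2 at 0.32 ± 0.61. In the 6 arrays alone with the block, the interval was 0.57 to 0.82 for TKTL1 and 0.62 to 0.93 for AKAP12. For CA2 it was 0.98 to 1.67 and for CMPK2 1.02 to 1.52. The intervals of TKTL1, AKAP12 and CMPK2 left out 1, but intervals are not adjusted for the number of genes, and none of these genes passed. The receptors were at -0.11 (PTGER1), 0.07 (PTGER2), -0.14 (PTGER3) and 0.10 (PTGER4), BIRC5 at 0.17 and CCND1 at -0.04. limma called 0 of 15281 genes, with or without the block, and in fits of the 6 arrays alone. At an unadjusted p under 0.05 there were 2 genes, 106 with the block, 10 in the 6 arrays alone and 470 in these with the block, against 764 that chance would give. Counts under the chance number show that these fits were conservative at 4 °C, so the counts do not speak against small responses. The smallest p of higher genes belonged to PRNT (0.31 ± 0.16), EXOC6B (0.42 ± 0.22), CEP128 (0.29 ± 0.16), MOGAT1 (0.37 ± 0.22) and CASTOR1 (0.44 ± 0.26), and of lower genes to CAV3 (-0.35 ± 0.15), LINC01550 (-0.36 ± 0.17), APBB2 (-0.29 ± 0.15), MAP3K14-AS1 (-0.34 ± 0.17) and GPR135 (-0.50 ± 0.28). None of these passed the adjustment (adjusted p = 1.00).

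The genes called at 37 °C were then followed as sets at 4 °C, where the arrays are other samples. The 282 higher genes averaged 1.58 at 37 °C and 0.02 at 4 °C, where 155 of them were above 0. The 154 lower genes averaged -0.97 and 0.04, and 56 of them were below 0 at 4 °C. By limma's fry over the samples at 4 °C, adjusted over both sets, neither set moved past the threshold (adjusted p = 0.88 for each, and 0.387 for each with the block). The correlation of log2 fold changes between the conditions, across 15281 genes, which are not independent replicates, was -0.09 (Pearson) and -0.14 (Spearman). The largest change of any gene at 4 °C was 0.68 in size. Of the 17 pathway lists 0 were called at 4 °C, by camera either way or by fry, and of the 10 marker lists 0. The camera count was 4 without replicate 1 of the drug group, 2 without replicate 2 of the vehicle group and 1 without its replicate 3. With the block the megakaryocyte list was called lower by camera (adjusted p = 0.0111), not with an estimated correlation (adjusted p = 0.302).

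Limits at 4 °C follow from 3 arrays per group and from the fit used. The median SE there was 0.321 in the main fit, 0.185 in the 6 arrays alone and 0.0982 in these with the block. In simulated data the main fit recovered 23.9% of 2-fold changes, and the fit of all arrays with the block 80.6%.

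**Figure D3:**
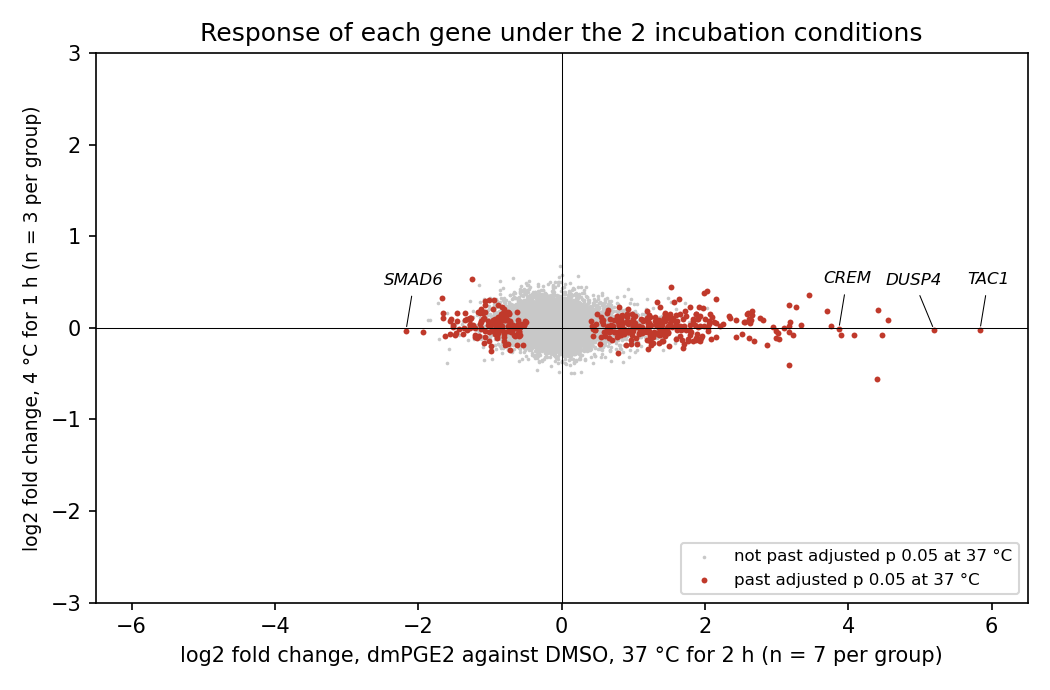
Log2 fold change of each gene with dmPGE2 at 37 °C (horizontal axis) and at 4 °C (vertical axis), with the 436 genes called at 37 °C in red and the others in grey. The genes spread to 5.84 along the horizontal axis and to 0.68 along the vertical one.

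The difference between the responses was tested directly. Larger rises at 37 °C than at 4 °C were found for TKTL1 (difference 4.95 ± 0.47, SE), SV2C (4.54 ± 0.51), LINC00473 (4.46 ± 0.39), GEM (4.21 ± 0.68), CXCL6 (4.15 ± 0.70), CREM (3.88 ± 0.51), NR4A2 (3.74 ± 0.61) and SIK1 (3.52 ± 0.30). ZNF331 (3.31 ± 0.48), PDE4B (3.08 ± 0.47), TNFRSF1B (2.94 ± 0.53), FOSL2 (2.47 ± 0.37), CXCR4 (1.89 ± 0.34) and NR4A1 (1.70 ± 0.30) passed too. In all 18 genes passed (limma), 18 higher and 0 lower. At an unadjusted p under 0.05 there were 534 genes, against 764 that chance would give. The fit without the block was thus conservative here, and its counts do not bound the number of differing responses in either direction. With every probe set tested, TKTL1 and SIK1 passed with 1 of 2 (others 0.97 and 0.09), and CXCR4 and NR4A1 with 1 of 3 (ranges 1.89 to 2.73 and 0.30 to 1.70). PDE4B passed with 2 of 3, and CREM and FOSL2 with 4 of 5. DUSP4 (5.23 ± 1.13, adjusted p = 0.0953), AKAP12 (3.58 ± 0.88, 0.198), CXCL1 (2.21 ± 0.46, 0.0756) and OSM (1.91 ± 0.38, 0.0504) did not pass with the probe set chosen, but did with the block (adjusted p = 1.43e-07, 0.000657, 0.000139 and 0.00043). Of DUSP4, 2 of 3 probe sets passed without the block when every probe set was tested (range 4.07 to 5.23). ANKRD37 (2.07 ± 0.63), VEGFA (1.84 ± 0.71) and CDKN1A (1.44 ± 0.34) passed only with the block (adjusted p = 5.83e-05, 0.0108 and 0.000442). With the block there were 1215, of which 419 were higher and 796 lower. Without 1 array of the drug group at 4 °C, replicate 1, the count was 10, and without replicate 5 of the drug group at 37 °C it was 30. The calls of CXCR4, NR4A1 and TNFRSF1B were each lost without any 1 of 4 of the 20 arrays (adjusted p up to 0.16, 0.133 and 0.16, without replicate 2 of the vehicle group at 4 °C). Without replicate 1 of the drug group at 4 °C, CXCL6, GEM and NR4A2 had adjusted p = 0.059, 0.059 and 0.0501.

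The lower responses with the smallest p did not pass: PRR15 (-1.18 ± 0.25), BMF (-1.64 ± 0.38), SLK (-1.12 ± 0.27), S100PBP (-1.31 ± 0.31) and SMAD6 (-2.14 ± 0.56). With the block they did (adjusted p = 0.00167, 0.000607, 0.00762, 0.00107 and 0.000128). PTGER4 differed by 1.73 ± 0.87 (adjusted p = 1.00, with the block 0.00922), whereas PTGER1 (0.21), PTGER2 (-0.47), PTGER3 (0.51), BIRC5 (-0.10) and CCND1 (0.48) passed in neither fit. Of the pathway lists, 7 differed by camera and 3 also with an estimated correlation: cyclic AMP targets, hypoxia and sterol synthesis. With the block these numbers were 8 and 4. Heat shock was added at the preset correlation (adjusted p = 0.0332). With an estimated correlation, immediate early genes and NF-κB targets were gained (adjusted p = 0.0447 each, without the block 0.0725 and 0.107) and hypoxia was lost (adjusted p = 0.109). Of the marker lists, dendritic cell genes were called at the preset correlation (adjusted p = 0.0481), not with an estimated one (adjusted p = 0.104). With the block the megakaryocyte list was called too (camera adjusted p = 0.047, and 0.348 with an estimated correlation). Temperature and time of incubation changed together.

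Vehicle samples were compared between the conditions as the background to these responses. At 37 °C the xenobiotic-metabolising enzyme CYP1B1 was 5.49 ± 0.60 higher on the log2 scale (SE, 7 against 3 samples), the chemokine CCL20 4.72 ± 0.51 and AHRR, a repressor of the aryl hydrocarbon receptor, 4.43 ± 0.34. ELFN2 (4.87), CLDN11 (4.28), DHRS2 (4.16), TRIM36 (4.06) and RASL10A (4.06) were also higher, although another probe set of ELFN2 passed as lower. For CLDN11, DHRS2 and TRIM36, 1 probe set passed of 2, 2 and 4, and others lay as low as -0.29, -0.03 and -0.26. MLLT3, a regulator of stem cell maintenance, was lower at -3.36 ± 0.52, along with ANKRD36 (-3.57), SNORA72 (-3.20), SLC8A1 (-2.88), KCNA3 (-2.73), H1-3 (-2.66), FIRRE (-2.64) and SLITRK4 (-2.62). SLC8A1 lost its call without any 1 of 8 of the 10 arrays (adjusted p up to 0.163) and after quantile normalisation (adjusted p = 0.0633), ANKRD36 without any 1 of 3 (up to 0.0697), and H1-3 without replicate 3 of the vehicle group at 4 °C (adjusted p = 0.0606). CCND1 was higher at 37 °C (2.41 ± 0.42) and CXCR4 lower (-0.72 ± 0.24, adjusted p = 0.0337), a call lost without any 1 of 5 arrays (adjusted p up to 0.168) and after quantile normalisation over all arrays (adjusted p = 0.0599). PTGER1 (-0.44), PTGER2 (-0.75), PTGER3 (-0.17), PTGER4 (-1.07), CREM (0.20), NR4A2 (-0.28) and BIRC5 (-0.58) did not pass with the probe set chosen. With every probe set tested, 3 of 4 of BIRC5 passed as lower (range -0.72 to -0.58), and 1 of 3 of PTGER1 and of PTGER3 did (lowest -0.54 and -0.53). Of CCND1 1 of 2 passed (other 0.19), of CXCR4 1 of 3 (others up to 0.07), of ANKRD36 1 of 2 (other -0.65) and of SLC8A1 2 of 3.

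In the vehicle comparison 4101 genes passed (limma), 1437 higher and 2664 lower at 37 °C. The direction depended on the scaling: after quantile normalisation over all arrays 2034 were higher and 1477 lower, and after centring each array on its median 2394 and 1085. The median of all genes was -0.15, and changes are relative to the deposited scale. Without replicate 1 or 2 of the vehicle group at 4 °C the count was 2386 (769 higher and 1617 lower) or 2558 (912 and 1646). Temperature, time and any difference in donors, handling or normalisation between the conditions cannot be told apart here.

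TGF-β, BMP and Notch genes had 12 of 21 higher and 0 lower in this comparison (14 higher adjusted over the list alone), among them the BMP targets ID3 (3.89 ± 0.33) and ID1 (2.74 ± 0.38) and the Notch targets HEY1 (2.98 ± 0.48) and HES4 (2.18 ± 0.34). camera gave an adjusted p of 1.73e-08, and 0.0219 with an estimated correlation. NF-κB targets and cytokines had 11 higher and 1 lower of 24, also adjusted over the list alone, including CCL4 (4.02 ± 0.57), CXCL1 (2.45 ± 0.32) and TNF (2.34 ± 0.35), with an adjusted p of 3.13e-07, and of 0.0764 with an estimated correlation. camera called none of the other 15 pathway lists or the 10 marker lists. fry, which does not compare a list with other genes, called 8 pathway lists, and of the marker lists those of B cells (adjusted p = 3.99e-05), dendritic cells (0.00183), mast cells with basophils and eosinophils (0.00183) and NK cells (0.0118), with medians of -0.45, -0.50, -0.79 and -0.63. Of primitive hematopoietic genes 8 of 23 were lower and 1 higher (9 and 1 adjusted over the list alone), with CD34 at -1.16 ± 0.24, FLT3 at -2.05 ± 0.47 and HLF at -1.87 ± 0.45 (camera adjusted p = 0.117). Among cyclic AMP targets 5 of 19 were lower and 1 higher (6 and 1 adjusted over the list alone), with SIK1 at -1.23 ± 0.21 (1 of 2 probe sets, other -0.20) and PDE4B at -1.72 ± 0.33. CDKN1A was higher (1.95 ± 0.24) and TOP2A lower (-2.00 ± 0.30) among cell cycle genes, of which 2 of 31 were higher and 6 lower, also adjusted over the list alone. SQLE (2.17 ± 0.37) and SREBF1 (2.31 ± 0.43) were higher in the sterol list, by 1 of 4 and 1 of 2 probe sets, with others down to -0.11 and -0.38.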

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

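The tests of fewer arrays, of a larger spread and of a scale difference between the conditions were chosen after the results they bear on had been seen.

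Single arrays at 37 °C lay far from the other 6 of their group for some of the genes named, a gap that chance alone gives in about 1 of 20 groups. Counted over the genes named in the text, 22 of 312 groups showed it. With dmPGE2, on the log2 scale, these were CXCL1 (8.43) and HLF (6.57) in replicate 3, CXCL3 (11.6), SLC8A1 (9.10) and TNF (8.07) in replicate 7, SLK (10.4) in replicate 2, NRARP (12.4) in replicate 1, CEP128 (6.12) in replicate 6, and DUSP2 (10.9), LMO2 (12.8), PLAUR (9.12), HSPA6 (14.7) and HSPH1 (13.5) in replicate 5. With vehicle they were CEP128 (6.85) in replicate 1, CXCL3 (9.66) and PTGER1 (7.17) in replicate 7, and DNAJA1 (13.7), DNAJB4 (10.9), HSPA6 (14.5), HSPH1 (12.9), PCDH8 (6.38) and PTGER3 (8.79) in replicate 5. CXCL3 lay high in both arrays of replicate 7, and 11 of the 22 values came from replicate 5.

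Responses to dmPGE2 that differed between 37 °C and 4 °C in the test of the difference itself (limma, log2 scale, response at 37 °C minus response at 4 °C) were found for TKTL1 (4.95), SV2C (4.54), LINC00473 (4.46), GEM (4.21), CXCL6 (4.15), CREM (3.88), NR4A2 (3.74), SIK1 (3.52), ZNF331 (3.31), PDE4B (3.08), TNFRSF1B (2.94), FOSL2 (2.47), CXCR4 (1.89) and NR4A1 (1.70). By camera, 7 lists differed, with a median difference of 1.73 for cyclic AMP and CREB targets, 0.68 for immediate early genes, 0.46 for TGF-β, BMP and Notch genes, 0.28 for hypoxia, 0.24 for NF-κB targets and cytokines, 0.21 for sterol synthesis and 0.13 for prostaglandin genes. Cyclic AMP targets, hypoxia and sterol synthesis were called also with an estimated correlation.

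Probe sets without a single gene symbol enter no comparison above. Among the 7884 of them kept by the filter, array controls left out, 208 passed at 37 °C (limma), 119 higher and 89 lower. With the replicate block 1886 passed. At 4 °C 0 passed in either fit.

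Other splits of the arrays were counted for each comparison. At 37 °C, 3 of 100 splits of the 14 arrays, the real one included, called as many genes. The real split gave 436 genes and the highest other 770, which points to a structure of the samples: the 2 other splits parted 3 of the pairs and the real one 7. Chance is argued against only by the splits that part as many pairs, where 1 of 64 is the smallest possible share. For the pathway lists 3 of 100 splits gave as many as the real 9, and the highest other gave 9. Among the 64 splits that part all 7 pairs, in the fit with the replicate block, 1 gave as many as the real 4380, and the highest other, with 1 pair exchanged, gave 783. Without the block the real split gave 436 and the highest of these others 0. For the difference between the conditions 1 of 100 splits gave as many as the real 18 (highest other 0), and for the vehicle groups 1 of 100 gave as many as the real 4101 (highest other 0). The splits for the difference exchanged drug labels within each condition without keeping the pairs parted. They ask whether the drug labels matter at all, and do not test whether the responses at 37 °C and 4 °C are equal. At 4 °C all 10 splits gave 0 genes like the real one, and 10 splits are too few for a share under 0.05.

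The absence of calls at 4 °C was weighed against 4 explanations. Fewer arrays alone would leave few calls at 37 °C too, but 3 arrays per group there gave at least 24 genes over 35 choices. This bears only on a response as large as that at 37 °C. For a smaller response it decides nothing. The fit without the block recovered 1.5% of 1.5-fold and 23.9% of 2-fold changes at 4 °C in simulated data. In blocked fits of each condition alone the median standard error at 4 °C was 0.908 times that at 37 °C, with fewer arrays, so the spread itself was not larger, although in the joint fit, which shares 1 estimate of the spread, fewer arrays give 0.155 against 0.102. If the response at 4 °C were as large as that at 37 °C, labels exchanged within a pair would give a pair difference of similar size. At 37 °C the higher genes differed by 1.35 to 1.80 per pair, whereas the largest difference at 4 °C was 0.043. With a small response or none, exchanged labels also give differences near 0, so for that case these values decide nothing. Temperature rather than time remains open and cannot be told apart, since 0 groups change 1 of them alone, so a response that needs 37 °C or a second hour is a candidate explanation that these arrays do not separate.

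The difference between vehicle groups was weighed in the same way. A scale difference between the conditions as the whole cause is argued against by 3511 genes called after quantile normalisation over all arrays, although the balance of directions turned. Probe effects fitted separately per condition may contribute: log2 fold changes of 2 probe sets of a gene correlated at 0.416 (95% interval 0.397 to 0.434, across 7571 genes, which are not independent), too near the bound of 0.4 to decide. For the drug comparison at 37 °C, which stays within a condition, the correlation over 7571 genes was higher, at 0.611 (95% interval 0.596 to 0.624). The cause of the lower agreement in the vehicle comparison was not tested. Other donors or another batch at 4 °C cannot be told apart from temperature and time, since 0 labels tie arrays of both conditions.

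Heat shock genes in replicate 5 at 37 °C stood apart in both groups. HSPA6 was at 14.7 with dmPGE2 and 14.5 with vehicle in replicate 5, and between 8.14 and 10.4 in the other arrays. A single probe set is argued against as the explanation, since the other 13 heat shock genes deviated from their group means by 1.783 and 1.786 in these arrays and by -0.551 to -0.124 in the others. The deviation was shared by drug and vehicle, and no biological explanation was tested. Without both arrays of replicate 5 the comparison at 37 °C called 458 genes.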

How the results depend on the processing

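The fit of the 14 or 6 arrays alone with the block, leaving out both arrays of a number, the block joined with another setting, and the check of numbers across conditions were chosen after seeing the data. At 37 °C the count of 436 stayed within 1.5 times under the filter, normalisation, mean of probe sets, variance model, array weights and 1.5-fold alternatives. It was 752 with every probe set on its own (29324 tested), 196 at adjusted p under 0.01, 93 with arrays 1 to 3 per group and 80 as the median over 35 choices of 3, where fewer samples lower it. Leaving out 1 array gave 295 to 463, and both arrays of a number 277 to 458, with 290, 285 and 277 without replicates 3, 4 and 6.

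With the replicate block it was 4380, 3679 over the 14 arrays alone, 2711 as the median over choices of 3 pairs, 1554 at least 1.5-fold, 4239 after quantile normalisation, 4318 after centring and 4394 with no filter. Without both arrays of a number the blocked count was 3740 (1), 4598 (2), 4384 (3), 3772 (4), 3996 (5), 3705 (6) and 3835 (7). At 4 °C every fit run gave 0, also without any 1 array (0 to 0).

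The difference between the conditions gave 32 genes with the mean of probe sets (31 higher, 1 lower), 38 with every probe set, 140 with array weights, 1215 with the replicate block and 1128 of these at least 1.5-fold, and 10 to 30 without 1 array. The vehicle comparison gave 6163 with no filter (19775 genes), 8553 with every probe set, 7953 with array weights, 2108 at adjusted p under 0.01, and 2386 to 4186 without 1 array. With the number shared across conditions as a replicate block it gave 6705, but these numbers do not pair the vehicle samples: deviations correlated at 0.197, 0.174 and -0.0727 for numbers 1 to 3. DNAJC3 there turned to -0.207 with the mean of its probe sets. The cause was not tested where neither the number of samples nor of features tested differs.

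Pathway lists at 37 °C were 4 with an estimated correlation, and 7 to 10 without 1 array. At 4 °C they were 0 to 4 without 1 array. The genes called at 37 °C averaged -0.0344 to 0.0768 (higher) and -0.0711 to 0.1178 (lower) at 4 °C without 1 array. Of the 65 genes named at 37 °C that passed, 5 lost their call in the fit of only the 2 groups compared and 2 with the mean of probe sets. After quantile normalisation 1 lost its call, and with the other variance model 1. All 65 passed with the block too. Of the genes taken by the rule that did not pass, 26 of 31 passed with it at 37 °C, 41 of 68 for the difference and 0 of 83 at 4 °C. By fry the block moved pathway lists from 8 to 13 at 37 °C and from 1 to 8 for the difference, and marker lists from 0 to 2 and from 0 to 1. Fitting only the groups compared is, for the difference, the same fit, and gave no separate value. Arrays carry no depth, and their number limits precision.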

Other observations

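The tests of AHR target, zinc finger and GIMAP genes and of centring, and the groups of genes in the next paragraph, were chosen after their values had been seen.

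Genes of clotting, clot lysis and the vessel wall were among those higher with dmPGE2 at 37 °C, picked from the calls and not from a list fixed beforehand. Thrombospondin THBS1 rose by 3.17 ± 0.54, thrombomodulin THBD by 2.80 ± 0.37, the tissue plasminogen activator PLAT by 2.44 ± 0.37, the urokinase receptor PLAUR by 2.35 ± 0.33 and endothelin EDN1 by 1.91 ± 0.32 on the log2 scale (SE, n = 7 per group, limma). Genes best known from neurons also rose: PCDH8 by 3.18 ± 0.46, HOMER1 by 2.87 ± 0.36, SGIP1 by 2.60 ± 0.44, NPTX1 by 2.55 ± 0.37 and SYT4 by 2.33 ± 0.59. Each of these 10 genes was higher in 7 of 7 pairs, and neither group was tested for enrichment.

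In vehicle samples the aryl hydrocarbon receptor targets CYP1B1 (5.49), AHRR (4.43), CYP1A1 (2.81) and TIPARP (1.98) were higher at 37 °C. The hypothesis that AHR target genes are higher at 37 °C was tested on the 3 members of a target list whose values had not been seen, and these gave p = 0.308 downward (camera, estimated correlation). All 3 lay below 0: ALDH3A1 (-0.47), which passed as lower (limma, adjusted p = 0.0266), and CYP1A2 (-0.37) and NQO1 (-0.21), which did not pass. As 0 of the 3 lay above the median level, the test decides nothing. The list of 7 members gave p = 0.0373 (camera, estimated correlation), which is not independent evidence because 4 of them prompted it.

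Under the replicate block at 37 °C, 126 of 416 zinc finger genes were lower (30.3%) and 26 higher, against 19.2% lower of 14865 other genes. camera gave p = 0.0506 with an estimated correlation. Of 6 GIMAP genes 5 were lower under the block and 0 passed without it (camera, p = 0.0406 with an estimated correlation). Both families were picked after their calls were seen, so these p-values test nothing independently. Under the block 67.3% of calls at 37 °C were lower after each array was centred on its median, but centring of the arrays moved this contrast by only -0.0034 and so decides nothing.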
